A study of Mus musculus with 12 samples.

How the data were processed

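RNA was measured by sequencing in 12 mouse heart samples, 3 in each of 4 groups: wild type and Csrp3 knockout, each at postnatal day 1 (P1) and postnatal day 21 (P21). Per the labels' protocols, total RNA was extracted with the miRNeasy micro kit and libraries were made with the Ovation Ultralow V2 kit. Groups and replicate numbers were taken from the sample titles, and each column was matched to its sample by the library name in the labels and the table's header. The column letter in the label of knockout P21 library 3 repeats that of knockout P1 library 1, so letters were not used. The labels give no strain, sex, litter or preparation date. The labels do not say that the 3 samples of a group came from separate animals. P-values therefore measure the spread between these samples, which may be partly technical.

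The authors deposited a single table of FPKM values (fragments per kilobase of gene, scaled to depth) for 56748 genes, with the symbol, coordinates and length of each gene. Per the submitters' processing notes, FastQC, TopHat2 2.0.13, Subread, featureCounts and edgeR were used, and 3 genome builds are named without a role. The build behind the table's coordinates is not given in the sources used here, so positions are printed as the table gives them. Whether the authors' counting used strand is not given in the sources used here either, so overlapping and antisense genes cannot be told apart.

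Each FPKM value times its gene length was a whole multiple of one step per library, within 0.05 of a read, for 100% of the nonzero values. The steps gave the number of reads in genes, which was 9.67 to 15.9 M (megareads) per library. They also showed that the authors had applied a scaling factor of between 0.605 and 1.17 per library on top of the read totals. FPKM is not a count, so the main test used log2 values at the scale deposited. A fold change is therefore on the log2(FPKM + 0.5) scale, which understates the change of genes with low values.

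Genes with an FPKM of at least 1 in at least 3 of the 12 libraries were tested, which left 13537 genes. A linear model with 1 mean per group was fitted to log2(FPKM + 0.5) of all 12 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, a trend on expression level and robust estimation. All adjusted p-values of single genes come from this test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The contrasts were knockout against wild type at each age, P21 against P1 in each genotype, and the difference between the knockout effects at P21 and at P1. Figures were drawn with matplotlib 3.10.9.

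The model was tested on simulated libraries that vary independently, with known changes in about 200 genes. The 46 nuclear genes of oxidative phosphorylation were also shifted, by 1 on the log2 scale. For the comparison at P1 it recovered 30.3% of genes changed by 1 on the log2 scale and 90.7% of those changed by 2. The corresponding shares were 36.7% and 81.4% at P21, 46.5% and 81.3% for age in wild type, 30.6% and 82.8% for age in knockout, and 8.25% and 56.7% for the difference of the knockout effects. At P21, 67 of the 12910 unchanged genes were called in the simulated data. Beside them, 36 of 98 genes changed by 1 and 79 of 97 changed by 2 were called. The share of false calls at P21 was therefore above what the threshold aims for, even if all 46 shifted genes were called too. Unchanged genes called numbered 25 for age in wild type, 5 for the difference, 1 for age in knockout and 0 at P1.

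Gene lists for 30 pathways and cell types that fit the postnatal heart, the cell cycle and p38 were written down in advance, with 715 of their 716 members found in the table. Each list was tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01 and adjusted over the 30 lists. The same test with a correlation estimated from the residuals stands beside it, as does fry, which tests whether the members of a list move on balance in 1 direction. The genes named were Csrp3, Rnf5 and Mapk14, and for each pair of groups the 10 higher and 10 lower genes with the largest change among those past the threshold. Those had to have a mean FPKM of at least 5 in the higher group, no overlap between the groups and an official name. Up to 4 members per list were added, those with the smallest adjusted p. Any other gene named was chosen after its values were seen, which the text says beside it.

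The groups, lists, naming rule, tests and a first set of alternatives were fixed before the data were examined. This set held other pseudocounts, filters, scalings and model options, the replicate number as a block, and leaving out each library in turn. Alternatives chosen after seeing the data were voom on the reads recovered from the FPKM values, sex as a covariate (from Xist), wild-type P21 libraries 1 and 2 left out together, the trend on gene length removed, and protein-coding genes alone. Reads were not realigned, and the deleted part of Csrp3 was not analysed here.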

Results

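The data are RNA sequencing profiles of mouse hearts at P1 and P21, from wild-type mice and from mice labelled as Csrp3 knockout, with 3 libraries per group. Csrp3 encodes muscle LIM protein, a protein of the sarcomere's Z disc. The title of the series ties Csrp3 to the entry of heart muscle cells into the mitotic cell cycle, by way of the ubiquitin ligase Rnf5 and p38 MAPK. Mean depth was 15.4 M (megareads) in genes for wild type at P1, 13.8 M for knockout at P1, 11.6 M for wild type at P21 and 12.5 M for knockout at P21.

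Csrp3 RNA was present in every library, including all 6 labelled knockout. In wild type its FPKM was 183, 179 and 238 at P1 and 1068, 1397 and 572 at P21. In the libraries labelled knockout it was 168, 94.3 and 147 at P1 and 671, 1112 and 926 at P21, with 4067 to 30709 reads per library. The log2 difference between the libraries labelled knockout and wild type was -0.58 (SE 0.37, adjusted p = 1) at P1 and -0.10 (SE 0.37, adjusted p = 0.920) at P21. With 1 library left out the value at P1 ranged from -0.75 (without knockout P1 library 1) to -0.33 (without knockout P1 library 2). At P21 it had no firm direction, at -0.47 without wild-type library 3, 0.18 without wild-type library 2, 0.10 without knockout library 1, 0.27 and 0.33 after the 2 rescalings and 0.63 against wild-type library 3 alone. The FPKM of the whole gene does not show whether its reads come from an intact transcript. The table gives Csrp3 on chromosome 7 from 48480146 to 48497781, on the minus strand. At P1 each library labelled knockout lay below each wild-type library (highest 168, lowest 179), and at P21 the genotypes overlapped. Because the RNA remains, the genotype is written below as labelled.

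**Figure D1:**
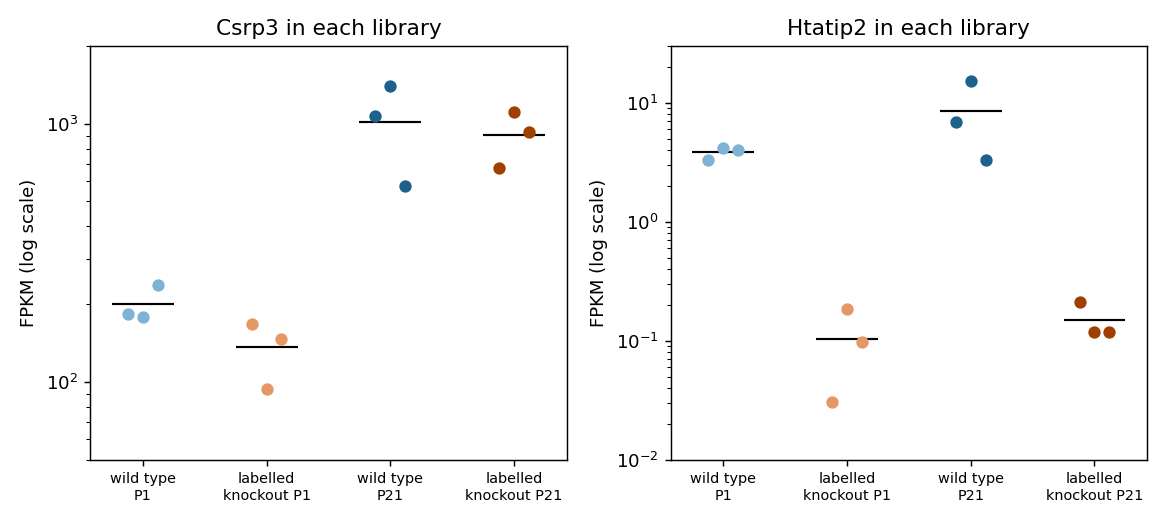
FPKM of Csrp3 (left) and Htatip2 (right) in each of the 12 libraries, on log axes; each point is a library and each line is the mean of 3. Csrp3 lies between 94.3 and 1397, with genotypes that overlap at P21 and lie next to each other without overlap at P1, while Htatip2 has a mean of 3.83 and 8.5 in wild type against 0.104 and 0.150 in the libraries labelled knockout.

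Libraries separated first by age. The first principal component held 60.2% of the variance and divided P1 from P21. The second held 12.5% and spread the P21 libraries, with wild-type P21 libraries 1 and 2 farthest from the others and knockout P21 library 2 between. The third held 8.20% and set wild-type P21 libraries 1 and 2 apart from each other, at -62.2 and 26.4, with knockout P21 library 2 at 25.6. Wild-type P21 library 2 correlated at 0.943 with knockout P21 library 2 and at 0.926 with wild-type P21 library 1. Wild-type P21 library 3 correlated at 0.965 and 0.958 with knockout P21 libraries 1 and 3. With wild-type P21 libraries 1 and 2 it correlated at 0.917 and 0.909. Correlations between libraries of a group, across genes on the log2 scale, were 0.963 to 0.982 for wild type at P1, 0.955 to 0.968 for knockout at P1, 0.909 to 0.926 for wild type at P21 and 0.935 to 0.962 for knockout at P21. At P1 the libraries did not sort by genotype. Knockout P1 library 2 correlated at 0.980 and 0.978 with wild-type P1 libraries 1 and 2. With knockout P1 libraries 1 and 3 it correlated at 0.963 and 0.968. Wild-type P1 library 3 correlated at 0.970 and 0.968 with knockout P1 libraries 1 and 3. With wild-type P1 libraries 1 and 2 its values were 0.963 and 0.968. Wild-type P21 libraries 1 and 2 had 10.2 and 9.67 M reads in genes and 17344 and 15811 genes above 0. The other 4 P21 libraries had 18348 to 20208 genes above 0. Per the labels, the library names of wild-type P21 libraries 1 and 2 end in R and those of the other 10 do not; what the letter means is not given in the sources used here.

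**Figure D2:**
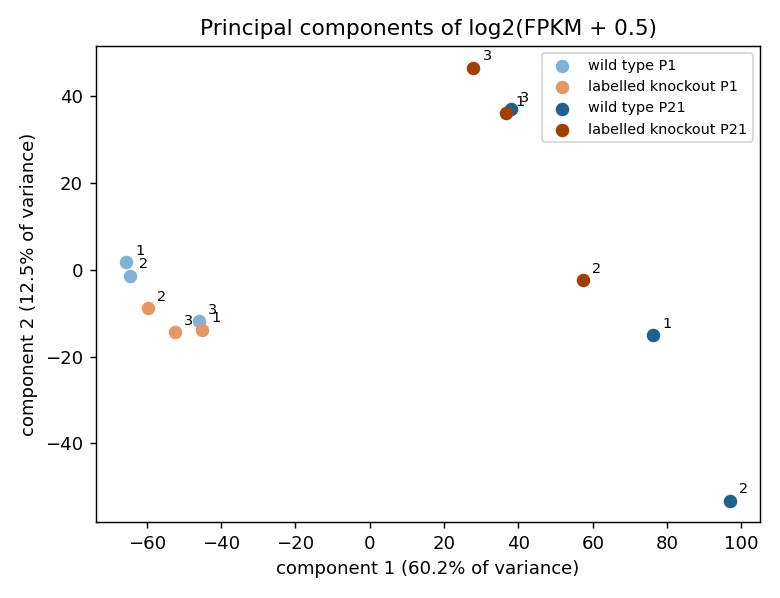
Position of each library on the first and second principal components of log2(FPKM + 0.5); numbers are the replicate numbers. P1 and P21 libraries lie apart on the first component (60.2% of the variance), and the P21 libraries are spread along the second (12.5%).

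The first comparison asked what differed at P1 between hearts labelled Csrp3 knockout and wild type. Genes of mitosis and of DNA replication had a median log2 change of -0.03 over 40 mitosis genes and 0.04 over 39 replication genes. The mitosis median moved from -0.40 (without knockout P1 library 3) to 0.61 (without knockout P1 library 1) when 1 library was left out, so it has no firm direction. Nuclear genes of oxidative phosphorylation were slightly higher in the libraries labelled knockout, by a median of 0.26 over 46 genes. Of these, 43 had a positive change and 0 passed the threshold (camera adjusted p = 1.1e-05, and 0.901 with an estimated correlation). The genotypes overlapped in this list. Relative to the mean of all 12 libraries, its median gene stood at -1.08, -1.09 and -0.72 in wild type. In the libraries labelled knockout it stood at -0.60, -0.75 and -0.68. Rnf5 (log2 change 0.09, SE 0.27) and Mapk14, which encodes p38 alpha (0.01, SE 0.19), both had an adjusted p of 1. The largest change in the neighbourhood of Csrp3 was in Htatip2, a gene 0.929 Mb away, at -2.84 (adjusted p = 0.170).

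With limma, 0 of the 13537 genes passed the threshold at P1. At an unadjusted p under 0.05 there were 82 genes, where 677 are expected by chance, and voom also called 0. That number was 431 with the P1 groups alone in the model and 997 with library weights, so it depends on the spread shared with the P21 libraries. The groups did not overlap for 7.96% of the genes, where chance gives 10%. A single gene, Htatip2, was called with a pseudocount of 0.1, after rescaling to TPM or without mitochondrial and the top 20 genes, with the P1 groups alone, with wild-type P21 libraries 1 and 2 left out, and with the length trend removed. Library weights gave 3.

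Among the gene lists at P1, camera called 5. With an estimated correlation 0 lists were called, and with fry 0. In the oxidative phosphorylation list Cycs, which encodes cytochrome c, was at 0.41 and Sdhb of complex II at 0.33. Markers of lymphocytes and neutrophils were higher by a median of 0.54 in 7 of 7 tested genes (adjusted p = 1.7e-06; adjusted p = 0.0959 with an estimated correlation), among them Ngp, a neutrophil granule gene, at 0.82 and the B cell gene Cd79b at 0.59. Extracellular matrix genes were lower by a median of -0.19 in 32 of 36 genes (adjusted p = 0.0021; adjusted p = 0.901 with an estimated correlation), with Eln (elastin) at -0.64 and Fn1 (fibronectin) at -0.46. Interferon-stimulated genes had a median of -0.19 (adjusted p = 0.0026; adjusted p = 0.831 with an estimated correlation), with Isg15 at -0.89. Sex-linked genes had a median of -1.42 (adjusted p = 0.0012; adjusted p = 0.341 with an estimated correlation). No member of these lists passed the threshold over all genes, and 0 did when adjusted over the list alone. The lymphocyte and neutrophil median ranged from 0.10 to 0.84 over the alternatives, with its camera call kept in 21 of 21.

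The 2 cell cycle lists at P1 depended on single libraries. Relative to the mean of all 12 libraries, the median mitosis gene stood at 1.75, 1.55 and 0.83 in wild type and at 0.05, 1.93 and 2.07 in the libraries labelled knockout. The adjusted p of the mitosis list was 3.8e-08 without knockout P1 library 3 and 1.8e-35 without knockout P1 library 1, and its median was 0.16 without wild-type P1 library 1 (adjusted p = 0.0281); it was also called, as lower, without wild-type P1 library 3 and without knockout P1 library 2. Replication genes ranged from -0.15 to 0.49 with 1 library left out and were called without wild-type P1 library 1, wild-type P1 library 2 or knockout P1 library 1 (adjusted p = 9.9e-23). With all libraries the adjusted p was 0.871 for mitosis and 0.213 for replication. The extracellular matrix call was lost without wild-type P1 library 1 and without knockout P1 library 1 (median -0.01). Per library the matrix list stood at 0.83, 0.50 and 0.07 in wild type. In the libraries labelled knockout it stood at -0.04, 0.59 and 0.24, so the genotypes overlapped. The interferon call was lost without wild-type P1 library 3 (median -0.06), without knockout P1 library 2 and with library weights, and the sex-linked call without wild-type P1 library 3 (median -0.99), with no filter, with library weights and with voom.

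With all libraries the other lists were not called at P1. Medians were 0.15 for the unfolded protein response (adjusted p = 0.0622; called at 0.20 without wild-type P1 library 1, and without knockout P1 library 3), 0.14 for hypertrophy and wall stress markers (adjusted p = 0.284; called at 0.15 without wild-type P1 library 1, adjusted p = 0.0281), -0.05 for the p38 pathway (adjusted p = 0.123), 0.00 for ER-associated degradation (adjusted p = 0.819) and -0.02 for cell cycle inhibitors (adjusted p = 0.871). Calls with 1 library left out also included IGF and neuregulin signalling (-0.29 without wild-type P1 library 3, adjusted p = 0.0026). Immediate early genes (-0.21 without knockout P1 library 1, adjusted p = 0.0044) and atrial markers (-0.28 without wild-type P1 library 2, adjusted p = 0.0340) were called as well. Wild-type P1 hearts held 1 library with Xist RNA and 2 with Y-linked RNA. Of the libraries labelled knockout at P1, 2 had Xist RNA, and library 3 had little of either kind, with 0.262 FPKM of Xist and 2.31 FPKM of Eif2s3y against 21.3 and 23.7 in the wild-type libraries with Y-linked RNA.

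The second comparison asked the same at P21, when heart muscle cells have largely left the cell cycle. Genes that mark hypertrophy and wall stress were higher in the libraries labelled knockout. Of 23 tested, 21 had a positive change and the median was 1.2 on the log2 scale. Fhl1, a LIM protein gene of stretched and hypertrophic muscle, rose from 43.9 ± 6.09 to 156 ± 43.5 FPKM (mean ± SD, n = 3 each). Hspb6, which encodes the small heat shock protein Hsp20, rose from 191 ± 71.2 to 685 ± 117 FPKM. Acta1, skeletal alpha-actin, went from 288 ± 293 to 1874 ± 699 FPKM and Nppa, atrial natriuretic peptide, from 242 ± 244 to 1110 ± 734, but neither passed the threshold.

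At P21, 9 genes passed the threshold, 8 higher and 1 lower. Those with an official name were Fhl1 (log2 change 1.78, SE 0.24, adjusted p = 0.0187), Hspb6 (1.88, SE 0.27, adjusted p = 0.0299), Mir7052 (4.72, SE 0.56, adjusted p = 0.0081) and, as the lower gene, Htatip2 (-3.56, SE 0.39, adjusted p = 0.0061). Mir7052 is a microRNA gene of 65 bases, and a high FPKM on so short a gene rests on few reads. The remaining 5 calls were gene models or pseudogenes outside the naming rule, among them Gm5417 and Ldha-ps2, named after their values were seen. Pseudogene values can come from reads shared with the parent gene. In the simulated data, with planted changes and more calls in all, 67 unchanged genes were called in this comparison. That number does not carry over to a comparison with 9 calls, but some of the 9 may be false despite their adjusted p. Csrp3 is above, Rnf5 was 10.7 ± 0.298 FPKM against 5.08 ± 1.74 in wild type (log2 change 1.06, SE 0.27, adjusted p = 0.170), and Mapk14 was -0.48 (SE 0.19, adjusted p = 0.315).

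The count at P21 rested on the wild-type libraries. At an unadjusted p under 0.05 there were 1863 genes, and the groups did not overlap for 11.95% of the genes, where chance gives 10%. Without wild-type P21 library 3 there were 1814 calls, without wild-type P21 library 2 there were 4, with libraries 1 and 2 of that group left out there were 2, and voom called 1. With the P21 groups alone in the model 0 genes passed, with 841 at an unadjusted p under 0.05. Of 21 alternatives, Htatip2 kept its call in 19, and of 22 alternatives Fhl1 kept it in 13 and Hspb6 in 8, with changes of 1.33 to 2.22 for Fhl1 and 1.31 to 2.32 for Hspb6. All 3 wild-type P21 libraries had Xist RNA (16.5, 5.54 and 21.3 FPKM), as had knockout P21 libraries 1 and 3 (19.6 and 19.4), while knockout P21 library 2 had 0.188 FPKM of Xist and 14.2 of the Y-linked gene Ddx3y. With sex as a covariate Fhl1, which is X-linked, and Hspb6 kept changes of 1.73 and 1.92 but did not pass (adjusted p = 0.0545 and 0.0579). Neither passed with the replicate number as a block (adjusted p = 0.0562 and 0.0594), so these losses do not single out sex.

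Hypertrophy and wall stress markers were the list with the clearest difference at P21. Camera gave an adjusted p of 3.6e-13, with adjusted p = 0.0332 with an estimated correlation and 0.0018 with fry, which called no other list at P21. Of the 23 genes, 2 rose over all genes and 18 when adjusted over the list alone. Per library, the median of the list relative to the mean of all 12 was -0.38, -0.16 and 0.05 in wild type and 0.81, 0.99 and 1.18 in the libraries labelled knockout. Against wild-type library 3 alone the median was 0.83. Nppa is also an atrial marker, and the atrial list varied within both groups. Its median was -1.33, -1.38 and 0.27 in wild type and -1.15, -1.43 and 1.18 in the libraries labelled knockout (list adjusted p = 0.473), and its log2 change was 0.16 with all libraries and -0.71 against wild-type library 3 alone.

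Extracellular matrix genes were higher by a median of 0.75, with 32 of 36 positive, 0 past the threshold over all genes and 9 when adjusted over the list alone (camera adjusted p = 8.9e-09; adjusted p = 0.602 with an estimated correlation). Cilp, a matrix protein gene, was at 2.26 (SE 0.45, adjusted p = 0.118) and the collagen gene Col8a1 at 1.84 (SE 0.33, adjusted p = 0.0757). Nuclear genes of oxidative phosphorylation were lower by a median of -0.61, with 41 of 46 negative, 0 past the threshold over all genes and 0 when adjusted over the list alone (adjusted p = 9.3e-07; adjusted p = 0.715 with an estimated correlation), among them Uqcrq of complex III at -1.32 and Atp5o of the ATP synthase at -1.16. Both medians moved with the wild-type libraries. Per library the oxidative phosphorylation list stood at 1.09, 2.11 and 0.28 in wild type and at 0.36, 0.99 and 0.07 in the libraries labelled knockout, and the matrix list at -1.22, -0.65 and -0.27 against -0.10, -0.11 and 0.31, without overlap. Against wild-type library 3 alone the median turned to 0.16 for oxidative phosphorylation and was 0.27 for the matrix. That comparison has no replicate in wild type at P21, so its spread comes from the other groups. The matrix kept its camera call in 22 of 22 alternatives, that comparison among them. The oxidative phosphorylation call was lost without wild-type P21 library 2, at a median of -0.22.

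Camera also called 3 lists of markers of other cell types at P21, each lost with an estimated correlation and with fry. Fibroblast markers had a median of 0.67 (adjusted p = 0.0094; adjusted p = 0.602 with an estimated correlation), with Col1a2 at 1.22 and Lum at 1.07. Endothelial markers had a median of -0.36 (adjusted p = 0.0094; adjusted p = 0.602 with an estimated correlation), which turned to 0.06 after rescaling without mitochondrial and the top 20 genes, with Ly6c1 at -1.49 and Emcn at -0.92. Epicardial markers had a median of 0.71 (adjusted p = 0.0210; adjusted p = 0.662 with an estimated correlation), with Upk3b at 1.62 and Aldh1a2 at 1.10. In these 3 lists 0 genes passed, also when adjusted over the list alone. The fibroblast call was lost without knockout library 3, with library weights and against wild-type library 3 alone (median 0.16, adjusted p = 0.430), and its median was 0.35 without wild-type library 1. Also lost were the endothelial call without wild-type library 1 (median -0.16) or knockout library 2, and the epicardial call without wild-type library 2, wild-type library 3 or knockout library 3 (median 0.19), with library weights, after both rescalings and against wild-type library 3 alone (0.45, adjusted p = 0.301).

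Cell cycle lists were not called at P21. Mitosis genes had a median of 0.17 (adjusted p = 0.195) and replication genes 0.16 (adjusted p = 0.143), with Ccnd1 (cyclin D1) at 1.82 and Ccnb2 (cyclin B2) at 1.04, both short of the threshold. The p38 pathway list had a median of 0.23 (adjusted p = 0.0926), with 0 genes past the threshold and 2 when adjusted over the list alone; the median was 0.13 without wild-type library 1 and 0.03 against wild-type library 3 alone (adjusted p = 0.697). Map2k6, a kinase upstream of p38, was at 1.06 (SE 0.18, adjusted p = 0.0704) and the transcription factor gene Elk1 at 0.83 (SE 0.20, adjusted p = 0.166). ER-associated degradation, the list that holds Rnf5, had a median of -0.06 (adjusted p = 0.947). Cell cycle inhibitors had a median of 0.21 (adjusted p = 0.397), which turned to -0.04 without wild-type library 2, adult sarcomere genes 0.16 (adjusted p = 0.125) and fatty acid oxidation -0.05 (adjusted p = 0.919). Adult sarcomere genes were called without wild-type library 2 (0.29, adjusted p = 0.0134) and were at 0.02 without wild-type library 3. Against wild-type library 3 alone, a comparison without replicates in wild type, they were at 0.32 and fatty acid oxidation was at 0.17. Pdk4, which restrains glucose oxidation, was at 3.05 (SE 0.54, adjusted p = 0.0704). Interferon-stimulated genes had a median of -0.18 (adjusted p = 0.0617; adjusted p = 0.715 with an estimated correlation), with 0 genes past the threshold and 2 lower when adjusted over the list alone. Against wild-type library 3 alone, without replicates in wild type, their median was -0.55, and without that library it was 0.03 (adjusted p = 0.779). Per library the interferon list stood at 0.56, 0.16 and 1.07 in wild type and at 0.49, 0.34 and 0.44 in the libraries labelled knockout. The list was called without wild-type library 1, wild-type library 2 or knockout library 1, and in some other alternatives, among them rescaling to TPM, where its median was 0.08.

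**Figure D3:**
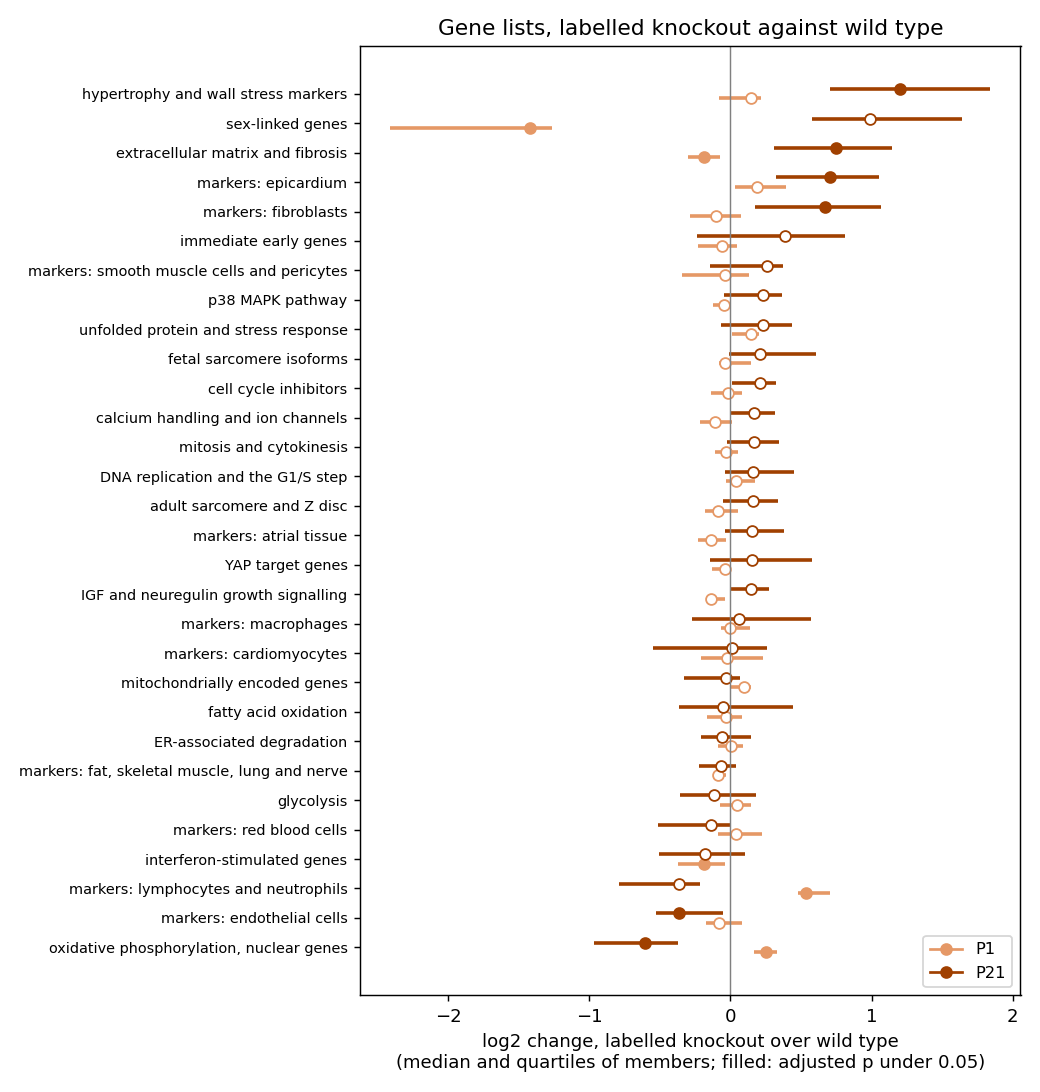
Median log2 change, with quartiles, of each of the 30 gene lists in libraries labelled knockout over wild type at P1 (light) and P21 (dark); filled circles are lists with an adjusted p under 0.05 by camera. Hypertrophy and wall stress markers lie at 1.2 at P21 and 0.14 at P1, and oxidative phosphorylation at -0.61 and 0.26.

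The third comparison followed wild-type hearts from P1 to P21. Genes of cell division fell: 39 of 40 mitosis genes and 33 of 39 replication genes were lower, among them Cdk1, the kinase that drives entry into mitosis (-4.01), Ccnb1 (cyclin B1, -3.95) and the replication licensing factor gene Mcm5 (-3.10). The fetal slow troponin I gene Tnni1 fell from 379 ± 32.8 to 0.460 ± 0.192 FPKM (n = 3 each), and the imprinted growth genes H19 (-5.80), Igf2 (-4.05) and Dlk1 (-4.60) fell with it. Of the nuclear genes of oxidative phosphorylation 41 of 46 rose, among them Cox7a1, a muscle subunit of complex IV, from 146 ± 31.7 to 4748 ± 3712 FPKM. Rpl3l, a ribosomal protein of striated muscle, rose from 5.41 ± 2.83 to 329 ± 107 FPKM, and Ckmt2, mitochondrial creatine kinase, from 66.4 ± 4.31 to 2053 ± 689.

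In wild type 6077 genes changed with age, 2917 higher and 3160 lower, and 3857 of these changed at least 2-fold. Sex is partly tied to age here, since wild-type P1 libraries 2 and 3 had Y-linked RNA and every wild-type P21 library had Xist RNA. With sex as a covariate 5488 genes were called, 5089 of them among the 6077. The groups did not overlap for 51.9% of the genes, where chance gives 10%. The other genes with the largest rise were Ly6a (5.69), Ly6c1 (4.84), Cbr2 (4.84), Tuba8 (4.61), Slc38a3 (4.56) and mt-Ts1, a mitochondrial transfer RNA gene (4.86). Strit1, which encodes a regulator of the calcium pump, was listed at 0 in all 3 P1 libraries and had a mean of 18.6 FPKM at P21. The other genes with the largest fall were Mest (-5.06), Bex4 (-4.79), Ptn (-4.75), Cited1 (-4.64) and Ccnb2 (-4.56). Cks2, a partner of cyclin-dependent kinases, and Mir186 had means of 22.4 and 11.8 FPKM at P1 and were listed at 0 in all 3 P21 libraries. Csrp3 rose by 2.26 (SE 0.37, adjusted p = 0.000827). Rnf5 fell from 11.3 ± 3.41 to 5.08 ± 1.74 FPKM (-1.09, SE 0.27, adjusted p = 0.0077). Mapk14 was higher by 0.66 (SE 0.19, adjusted p = 0.0158), a direction that turned with another scaling, to -0.46 after rescaling to TPM and -0.33 without mitochondrial and the top 20 genes.

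The split between higher and lower genes depended on the scaling of the libraries. After rescaling to TPM, 9164 genes were called, 756 higher and 8408 lower, and without mitochondrial and the top 20 genes 8114 were called, 868 higher and 7246 lower. After rescaling to TPM the median of all genes was -1.10 in wild type and -0.65 in the libraries labelled knockout, against -0.04 and -0.02 at the scale deposited, so changes smaller than these have no firm direction; for knockout against wild type it gave a median of 0.34 at P21 and -0.10 at P1. With wild-type P21 libraries 1 and 2 left out, 3001 genes were called, 2723 of them among the 6077.

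Lists that fell in wild type by camera were mitosis (median -2.85, adjusted p = 1.0e-14), replication (-1.71, adjusted p = 1.2e-11), IGF and neuregulin signalling (17 of 21 lower, -1.89, adjusted p = 1.6e-08), epicardial markers (9 of 10 lower, -2.30, adjusted p = 7.1e-05), extracellular matrix (20 of 36 lower and 2 higher, -1.27, adjusted p = 0.000512) and atrial markers (4 of 16 lower, -1.75, adjusted p = 0.0273). Postn (periostin) fell by 4.09 and Fn1 by 2.70. Lists that rose were oxidative phosphorylation (2.13, adjusted p = 4.7e-14), interferon-stimulated genes (14 of 21 higher, 1.11, adjusted p = 9.4e-06), macrophage markers (9 of 14 higher, 1.14, adjusted p = 0.000688), adult sarcomere and Z disc genes (16 of 28 higher and 2 lower, 0.90, adjusted p = 0.000127), endothelial markers (9 of 18 higher and 2 lower, 0.67, adjusted p = 0.0063), mitochondrially encoded genes (7 of 13 higher, 1.22, adjusted p = 0.0167), glycolysis (12 of 26 higher and 3 lower, 0.79, adjusted p = 0.0167) and red blood cell markers (5 of 7 higher, 2.70, adjusted p = 0.0273). With an estimated correlation each of these calls was lost, at an adjusted p of 0.445 to 0.691 (adjusted p = 0.445 for mitosis and 0.480 for oxidative phosphorylation). That test called 0 lists with age in either genotype, not even mitosis, where nearly all genes passed the threshold. A call lost with it therefore does not show that a list was unchanged. After rescaling to TPM the medians of adult sarcomere genes (-0.24), glycolysis (-0.22) and endothelial markers (-0.43) turned negative, so the sign of these changes depends on the scaling. Their camera calls, which are relative to other genes, were kept there. Oxidative phosphorylation was at 1.22 with wild-type P21 libraries 1 and 2 left out. Fry called 18 lists, among them each of these except atrial markers (adjusted p = 0.0643).

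Adjusted over the list alone, the wild-type counts with age were 39 lower for mitosis, 33 lower for replication, 42 higher for oxidative phosphorylation, 18 lower for IGF and neuregulin signalling, 22 lower and 2 higher for the extracellular matrix, and 16 higher for interferon-stimulated genes. Fatty acid oxidation split evenly, with 9 of 32 genes higher, among them Lpl (lipoprotein lipase, 1.82), and 9 lower, among them Cpt1a (-2.17). The p38 pathway also moved both ways, with 10 of 26 genes higher, such as Map2k3 (1.55), and 7 lower, such as Map2k6 (-1.96). With single libraries left out, calls were lost without wild-type P1 library 3 (red blood cells, glycolysis, atrial markers), wild-type P21 library 3 (red blood cells, mitochondrially encoded genes) and wild-type P21 library 1 or 2 (atrial markers, median -1.38 without library 2). Against wild-type P21 library 3 alone the atrial median was -0.16, and the red blood cell list stood at 2.84 in wild-type P21 library 2 against 0.12 and 0.73 in libraries 1 and 3.

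The fourth comparison followed hearts labelled knockout from P1 to P21. Cell division genes fell here as well, with 38 of 40 mitosis genes (median -2.63) and 33 of 39 replication genes (median -1.55) lower. Acta1 rose from 25.7 ± 11.4 to 1874 ± 699 FPKM (n = 3 each, log2 change 6.17), and Xirp2, which encodes a protein of the intercalated disc, by 5.41. Of the 23 hypertrophy and wall stress markers, 15 rose and 0 fell. Tnni1 (-8.67) and H19 (-6.17) fell. Oxidative phosphorylation genes were higher in 17 of 46 cases over all genes and in 31 when adjusted over the list alone, with Cox7a1 from 188 ± 22.7 to 1647 ± 832 FPKM.

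In the libraries labelled knockout 3388 genes changed with age, 1599 higher and 1789 lower, of which 2102 changed at least 2-fold. The groups did not overlap for 47.4% of the genes, where chance gives 10%. Other genes with the largest rise were Rpl3l (5.57), Ckmt2 (4.93), Cbr2 (4.87), Art1 (4.85), Tuba8 (4.76), Plet1os (4.48) and Trim72, a membrane repair gene (4.41). Other genes with the largest fall were Bex4 (-4.80), Cited1 (-4.77), Dlk1 (-4.56), Bmp7 (-4.36), Mest (-4.29) and Plagl1 (-4.14). Mir503 had a mean of 10.8 FPKM at P1 and was listed at 0 in all 3 P21 libraries. Csrp3 rose by 2.73 (SE 0.37, adjusted p = 0.00047). Rnf5 was -0.12 (SE 0.27, adjusted p = 0.795) and Mapk14 0.17 (SE 0.19, adjusted p = 0.553).

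This count moved with the settings too. After rescaling to TPM 5543 genes were called, 630 higher and 4913 lower, and without mitochondrial and the top 20 genes 3202 were called, 669 higher and 2533 lower. Without knockout P1 library 2 there were 2085 calls and without knockout P21 library 1 there were 2220, while library weights gave 6773.

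By camera the lists that fell in the libraries labelled knockout were mitosis (adjusted p = 9.7e-20), replication (adjusted p = 1.1e-15), IGF and neuregulin signalling (16 of 21 lower, -1.58, adjusted p = 6.5e-09) and epicardial markers (8 of 10 lower, -1.85, adjusted p = 1.9e-05). Lists that rose included oxidative phosphorylation (1.13, adjusted p = 2.2e-10), adult sarcomere genes (19 of 28 higher, 1.19, adjusted p = 2.2e-09), interferon-stimulated genes (12 of 21 higher, 1.04, adjusted p = 7.7e-08), hypertrophy and wall stress markers (1.47, adjusted p = 3.0e-07), macrophage markers (11 of 14 higher, 1.37, adjusted p = 8.0e-07) and mitochondrially encoded genes (4 of 13 higher, 1.23, adjusted p = 0.0061). Immediate early genes (9 of 20 higher and 1 lower, 0.74, adjusted p = 0.0122), cardiomyocyte markers (8 of 17 higher and 2 lower, 1.05, adjusted p = 0.0132), endothelial markers (7 of 18 higher and 1 lower, 0.49, adjusted p = 0.0166), red blood cell markers (5 of 7 higher, 1.98, adjusted p = 0.0113), glycolysis (10 of 26 higher and 3 lower, 0.54, adjusted p = 0.0204) and fibroblast markers (4 of 14 higher, 0.56, adjusted p = 0.0321) rose as well. With an estimated correlation these calls were lost, at an adjusted p of 0.128 for hypertrophy and wall stress markers and adult sarcomere genes and up to 0.417 for the rest. After rescaling to TPM the medians of glycolysis (-0.12), endothelial markers (-0.17) and fibroblast markers (-0.06) turned negative. Fry called 21 lists, among them each of these. Adjusted over the list alone, 39 mitosis genes and 37 replication genes were lower, and 16 hypertrophy and wall stress markers, 23 adult sarcomere genes and 17 interferon-stimulated genes were higher. The fibroblast call was lost without knockout P1 library 1 or knockout P21 library 3, the glycolysis call without knockout P1 library 1 and the endothelial call without knockout P21 library 3 (median 0.35).

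Of the genes that changed with age, 2928 changed in both genotypes, 1339 higher in both, 1586 lower in both and 3 in opposite directions. Independent lists of these sizes would share 345 higher and 418 lower genes. These comparisons share no library, but both take the spread of each gene from the same fit of all 12 libraries. Their calls are therefore not independent, and 345 and 418 do not give the overlap by chance. A further 3149 genes passed in wild type alone and 460 in the libraries labelled knockout alone, which does not show that they differ between the genotypes. The median absolute change was 0.64 in wild type and 0.44 in the libraries labelled knockout. On the first component wild-type P21 libraries 1 and 2 lay farthest from P1, at 76.3 and 96.9. The other P21 libraries lay at 27.9 to 57.3. The larger median change in wild type therefore cannot be told apart from an effect of those 2 libraries. The correlation of the changes with age in the 2 genotypes, across genes, was 0.835. Genes are not independent replicates.

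The last comparison asked whether the knockout effect differed between the ages. Differences among the genes named included Pdk4 (3.46, SE 0.77), Acta1 (3.03, SE 1.05) and Cilp (2.33, SE 0.64), all higher at P21 relative to P1, each with an adjusted p of 0.687. Rnf5 differed by 0.97 (SE 0.38, adjusted p = 0.687), Mapk14 by -0.49 (SE 0.27, adjusted p = 0.687) and Csrp3 by 0.48 (SE 0.52, adjusted p = 0.805). With limma 0 genes passed, with 940 at an unadjusted p under 0.05 and 0 by voom. Without wild-type P21 library 3 there were 293 calls. Mitosis genes differed by a median of 0.18 (adjusted p = 0.268) and replication genes by 0.11 (adjusted p = 0.551), but without knockout P1 library 1 they differed by -0.39 (adjusted p = 0.000228) and -0.23 (adjusted p = 0.0187), and without knockout P1 library 3 by 0.58 (adjusted p = 0.000389) and 0.37 (adjusted p = 0.0426). Knockout effects at P1 and at P21 had a Pearson correlation of -0.173 and a Spearman correlation of -0.208 across genes, and the Pearson correlation was 0.130 with wild-type P21 libraries 1 and 2 left out.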

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

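Tests chosen only after the result was seen were the label test on Csrp3 and the comparison of stretches of genes without Htatip2, which replaced tests that rested on Htatip2, the removal of the length trend, the comparison with wild-type P21 library 3 alone as a setting, and the count with wild-type P21 libraries 1 and 2 left out of both genotypes.

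Lists of genes whose knockout effect differed between P21 and P1, by camera on the difference itself, were hypertrophy and wall stress markers (1.26, adjusted p = 5.4e-10; adjusted p = 0.0834 with an estimated correlation), extracellular matrix (0.93, adjusted p = 3.1e-10; adjusted p = 0.475 with an estimated correlation), nuclear oxidative phosphorylation (-0.87, adjusted p = 1.0e-09; adjusted p = 0.654 with an estimated correlation), lymphocyte and neutrophil markers (-1.18, adjusted p = 0.000318; adjusted p = 0.211 with an estimated correlation), fibroblast markers (0.65, adjusted p = 0.00896; adjusted p = 0.529 with an estimated correlation), the p38 pathway (0.26, adjusted p = 0.0273; adjusted p = 0.442 with an estimated correlation) and sex-linked genes (2.41, adjusted p = 0.0464; adjusted p = 0.529 with an estimated correlation). In each list 0 genes passed with limma for the difference, where 940 of all genes had an unadjusted p under 0.05 and voom called 0. Lymphocyte and neutrophil markers rest on 7 genes with low values. With wild-type P21 libraries 1 and 2 left out the calls of oxidative phosphorylation (-0.08, and -0.43 without library 2 alone), fibroblasts (0.31) and the p38 pathway (0.06) were lost. In that alternative, without replicates in wild type at P21, the difference was 0.78 for hypertrophy and wall stress markers and 0.47 for the matrix. It was -0.82 for lymphocyte and neutrophil markers and stayed at 2.41 for sex-linked genes, whose call was lost as well. The p38 call was also lost with the length trend removed and among genes with a mean FPKM of at least 5, and the fibroblast call with library weights. Sex-linked genes kept their call in 10 of 26 alternatives (1.5 without knockout P21 library 2), and they follow the mix of sexes, which differs between the groups.

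Csrp3 RNA remained in the libraries labelled knockout, and beside Csrp3 on chromosome 7 Htatip2 passed the threshold at P21 (-3.56, adjusted p = 0.0061) but not at P1 (-2.84, adjusted p = 0.170). Swaps among the 12 libraries as the reason why the RNA remains are argued against, if the allele removes the RNA. The lowest wild-type library had 0.515 of the Csrp3 FPKM of the highest library labelled knockout at its age. Other swaps stay open, because Htatip2 was picked for parting the genotypes. Of 200 relabellings within age, the real one included, 6 had a gene parted 4-fold. Within 10 Mb of Csrp3, 6 of 121 genes (4.96%) parted the genotypes in the same direction at both ages, against 0.455% elsewhere and 0.5% by chance. Without Htatip2, which prompted the test, 5 of 120 remain (4.17%), above 99.99% of 10874 equally long stretches and equal to the highest. The stretches overlap, each starting 1 gene after the last, so far fewer of them are independent and 99.99% overstates the precision. These 6, named after their values were seen, were Htatip2, Hps5, Gtf2h1, Kcnj11 and Gm32031 (lower) and Tubgcp5 (higher), of which those other than Htatip2 had adjusted p of 1 at P1 and 0.168 to 0.433 at P21, and a strain segment carried along with the Csrp3 allele may explain them. Which part of Csrp3 was deleted, and whether the remaining RNA can be translated, was not tested, and an effect of Csrp3 loss on its neighbours stays open.

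At P21 camera called hypertrophy markers and the extracellular matrix higher and oxidative phosphorylation lower in the libraries labelled knockout, with adjusted p = 0.0332, 0.602 and 0.715 with an estimated correlation and 2, 0 and 0 genes past the threshold. A trend on gene length as the whole cause is argued against, since with it removed the medians were 1.21, 0.72 and -0.53. Wild-type P21 libraries 1 and 2 stand apart from the rest, on the third component also from each other, and alone have names that end in R. They may account for the oxidative phosphorylation difference and for much of the matrix difference. Against wild-type library 3 alone, without replicates in wild type at P21, the medians were 0.16 and 0.27. For hypertrophy markers that median was 0.83, between the bounds set for the test. Wild-type library 3 correlated more closely with knockout P21 libraries 1 and 3 than with wild-type P21 libraries 1 and 2. For all of these lists the share of wild-type P21 libraries 1 and 2 therefore cannot be told apart from genotype. An effect of genotype on wall stress stays open, as does another preparation of the 2 libraries, which the letter leaves possible.

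More genes were called from P1 to P21 in wild type (6077) than in the libraries labelled knockout (3388), but 4288 against 4039 with only the groups compared and 5925 against 6773 with library weights. A trend on gene length as the whole cause is argued against, since the ratio was 1.64 with it removed and 1.79 without. With wild-type P21 library 3 alone 3001 genes were called, against at most 1243 with 1 knockout P21 library alone, which passed the bound written in advance against libraries 1 and 2 as the cause. That bound was unsuited, because leaving out those 2 libraries also removes their spread from the shared estimate: the same knockout libraries then called 3074, 4664 and 2767, and all 3 together 4986. On this second basis, chosen after that outcome was seen, the wild-type count lay below the highest count with 1 knockout P21 library. The basis is not matched either. Those knockout counts also lack the spread of 2 knockout P21 libraries, which stays in the fit behind the wild-type count. The counts therefore cannot decide whether wild-type P21 libraries 1 and 2 explain the larger wild-type count. A difference in maturation between the genotypes stays open as well.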

How the results depend on the processing

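Alternatives chosen only after the data were seen were voom, sex as a covariate, wild-type P21 libraries 1 and 2 left out, the length trend removed and protein-coding genes alone. The count at P1 was 0, and 1 with a pseudocount of 0.1, after rescaling to TPM, after rescaling without mitochondrial and the top 20 genes, with only the groups compared, with wild-type P21 libraries 1 and 2 left out and with the length trend removed; library weights gave 3, and leaving out 1 library gave 0 each time. At P21 the count of 9 became 14 with a pseudocount of 1, 5 with no filter and 4 among genes with a mean FPKM of at least 5 (other numbers of genes tested), 14 after rescaling to TPM, 0 with only the groups compared, 19 without trend and robust estimation, 1 with voom and 2 with wild-type P21 libraries 1 and 2 left out; it ranged from 4 to 1814 with 1 library left out (4 without wild-type library 2, 1814 without wild-type library 3). With age in wild type the count of 6077 became 3349 among genes with a mean FPKM of at least 5, 9164 after rescaling to TPM and 3001 with wild-type P21 libraries 1 and 2 left out, and ranged from 4268 to 7019 with 1 library left out. In the libraries labelled knockout the count of 3388 became 1815 with the same filter, 5543 after rescaling to TPM and 6773 with library weights, and ranged from 2085 (without knockout P1 library 2) to 2768 with 1 library left out. With the replicate number as a block the counts were 0, 7, 5995 and 3249. With group means removed, pairs of libraries from different groups with the same number correlated from -0.297 to 0.491 and those with other numbers from -0.475 to 0.342. Of the 12 libraries, 7 correlated best with one of their own number. Genes whose knockout effect differed between ages ranged from 0 to 293 with 1 library left out (293 without wild-type P21 library 3). The correlation of the knockout effects at the 2 ages was -0.173, -0.333 among genes with a mean FPKM of at least 5, -0.330 with sex as a covariate, 0.130 with wild-type P21 libraries 1 and 2 left out, and -0.257 to -0.0228 with 1 library left out. The Csrp3 difference stayed short of the threshold in every alternative run at both ages, while its direction at P21 turned in some (0.63 with wild-type P21 libraries 1 and 2 left out).

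Reversed directions after rescaling to TPM were those of Derl2 (-0.060), Cidea (-0.19), Axl (-0.34), Ube2g2 (-0.42) and Mapk14 (-0.46) with age in wild type and Axl with age in the libraries labelled knockout (-0.13); without mitochondrial and the top 20 genes the wild-type values were -0.057 for Cidea, -0.20 for Axl, -0.28 for Ube2g2 and -0.33 for Mapk14. After rescaling to TPM, list medians also turned: with age in wild type adult sarcomere (-0.24), glycolysis (-0.22) and endothelial markers (-0.43), in the libraries labelled knockout glycolysis (-0.12), endothelial (-0.17) and fibroblast markers (-0.06). The shift of all genes by the rescaling shows the cause. With 1 library left out, mitosis genes ranged from -0.40 to 0.61 for the knockout effect at P1 (0.16 without wild-type P1 library 1) and from -0.39 to 0.58 for the difference between ages, where replication genes ranged from -0.23 to 0.37. With wild-type P21 libraries 1 and 2 left out, the knockout effect at P21 was 0.16 for oxidative phosphorylation and -0.71 for atrial markers. For these lists the cause was not tested. Depth of 9.67 to 15.9 M reads limits genes with low FPKM, of which only those with at least 1 in 3 libraries were tested.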

Other observations

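The tests of other splits reported here were all chosen in advance. Of the splits of 6 libraries into 3 and 3 there are 10, too few for a share under 5%. At P1 the real count was 0 (highest other 2), so 10 of 10 splits reach it by construction and nothing follows about chance. At P21, 2 of 10 did (real 9, highest other 2075). The split with 2075 calls put wild-type P21 libraries 1 and 2 together with knockout P21 library 2, which points to a structure of the samples other than genotype. With age, 1 of 10 did in wild type (real 6077, highest other 0) and 1 of 10 in the libraries labelled knockout (real 3388, highest other 1). For the difference of the knockout effects the real count was also 0 (highest other 2183, which again points to a structure of the samples), so 100 of 100 relabellings drawn within age reach it by construction and nothing follows about chance.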
